A study of Drosophila melanogaster with 4 samples.

How the data were processed

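The series measured where the histone variant H2Av lies on the genome of Drosophila melanogaster, by chromatin immunoprecipitation followed by sequencing (ChIP-seq). Chromatin came from nuclei of late larvae of the wild-type strain Oregon-R, crosslinked with formaldehyde and sheared by sonication, and H2Av was precipitated with an antibody against it. H2Av is the only H2A variant of this fly and takes the roles that H2A.Z and H2A.X have in other animals. The labels name 2 ChIP libraries and 2 input libraries of sonicated chromatin without precipitation. They do not say whether the replicates came from separate collections of larvae, so the spread between replicates given here may be technical.

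The deposited data used here are 3 lists of enriched regions, 1 for each ChIP replicate and 1 for the whole series, called the combined list. Each replicate list is tied by the labels to the input library of the same replicate number. The input libraries have no list of their own and enter only through the regions called against them. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes, and positions are on FlyBase release 5, per the file headers. The peak caller, its threshold, its filters and the way the replicates were combined are not given in the sources used here. The value of each region is the authors' score, a positive number whose definition and scale are not given in the sources used here. Scores were therefore used to rank, filter and describe regions within 1 list, and between lists only in correlations across matched regions and in their ranks. Read depth is unknown, so no value has a depth-based error, and the number of regions called can move with depth and threshold.

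The choice of tests, alternatives and named regions was fixed before the data were examined. Exceptions are named where the text says that a choice was made after seeing the data or was not in the plan. Sequence lengths were taken from the file headers. Regions running past the end of their sequence (2 in replicate 1, 1 in replicate 2 and 2 in the combined list) were counted up to the end when bases were summed. Comparisons of the replicates used the arms X, 2L, 2R, 3L and 3R and chromosome 4. The 6 scaffolds of unplaced heterochromatin of a known chromosome (2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet) and the pooled sequence U were described apart. Uextra is listed in the headers but holds no region in any list.

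A region counted as shared when it overlapped a region of the other list by at least 1 bp. Chance overlap and the Jaccard index of bases were taken from 1000 circular shifts of 1 list along each arm, 1-sided for more overlap, and the smallest p these shifts can give is 0.001. Shares of regions carry exact Clopper-Pearson 95% intervals, which cover counting error only, since neighbouring regions are not independent. Scores were compared by Spearman and Pearson correlation across regions matched 1 to 1, with 2-sided permutation tests of 100000 resamples, whose smallest p is 1e-05. Coverage is the percent of bases in regions, given per replicate and as mean ± SD over the 2 replicate lists. Chromosome 4 was set against all non-overlapping stretches of its own length on the 5 major arms. X was set against the autosomal arms over windows of 1 Mb, with a 2-sided permutation test and a bootstrap interval from 10000 draws. Broad regions, of at least 10 kb, were compared by Fisher's exact test. The assembled arm ends next to the centromere, stretches without regions, broad regions and scores by class of sequence were chosen after seeing the data. The plan gave coverage of the arms as values without a test. The tests of chromosome 4 and of X, and the correlations of window coverage, were not in it. Benjamini-Hochberg adjustment was applied within each family of tests named in the text.

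The overlap and window tests were tested on simulated data. Of 100 pairs of independent simulated lists of 4329 regions, 2% were called at 0.05. From simulated lists with 49.9% of regions copied, 49.8% (SD 0.493) was recovered once chance overlap was taken off. The shares reported for the deposited lists count every overlap, chance included, and their regions vary in width and cluster along the arms. The recovered share is therefore no check of the reported shares. With no difference put in, the window test called 7% of 100 sets of 117 windows, and with 10 points put in it called 100%. Each set was the observed windows shuffled, so a rate near 0.05 without a difference is given by construction. The shuffle does not keep the likeness of neighbouring windows, and differences under 10 points were not simulated.

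The gene table at hand is on release 6 of the genome and its coordinates were not used with release 5 positions. The planned results on genomic features, start sites, marked genes and gene lists were therefore not made, none of the 22 gene lists fixed in advance was tested, and regions are named by position alone. The rule for named regions, for the case without gene positions, took the 10 highest-scoring and the 5 widest regions of the combined list that overlap both replicate lists. Alternatives were another minimum overlap, the higher-scoring 50% of each list, lists cut by score to the length of the shorter, other windows, each replicate left out, and the combined list. Both cuts by score were made over all sequences, so the lists still differed in length on the arms and chromosome 4. Calculations used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, and figures matplotlib 3.10.9.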

Results

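H2Av-enriched regions took up a large part of the release 5 genome in larval nuclei, more in replicate 1 than in replicate 2. The list of ChIP replicate 1 held 9667 regions over 37.3 Mb, or 26.7% of the sequence that carried regions. The list of ChIP replicate 2 held 4664 regions over 25.04 Mb, or 17.9%. The combined list of the series held 7944 regions over 36.2 Mb, or 25.9%. Regions of replicate 1 were narrower, with a median width of 2541 bp against 3661 bp in replicate 2 and 2811 bp in the combined list. Broad regions of at least 10 kb made up 5.87% of replicate 1, 12.3% of replicate 2 and 9.74% of the combined list. Their numbers were 567, 572 and 774, so the replicates differed in the share of broad regions and hardly in their number. Wider regions had higher scores on the arms and chromosome 4, with a Spearman correlation across regions of 0.72 in replicate 1, 0.73 in replicate 2 and 0.72 in the combined list. Regions are not independent replicates. The values come from 2 ChIP libraries, and the depth behind either is unknown.

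The replicate lists marked largely the same places on the arms and chromosome 4. Of 4329 regions of replicate 2, 4117 overlapped a region of replicate 1, which is 95.1% (95% Clopper-Pearson interval 94.4 to 95.7). Circular shifts gave 46.6% on average and 54.8% at most, so the observed share was 2.04 times chance (permutation p = 0.001, the smallest the shifts can give, 1-sided). In the other direction 4629 of 8402 regions of replicate 1, or 55.1% (54.0 to 56.2), were shared against 28.7% by shifting, which is 1.92 times chance (permutation p = 0.001, also the smallest). Regions of both lists shared 20.9 Mb, which was 63.7% of the bases of replicate 1 and 87.9% of those of replicate 2. The Jaccard index of bases was 0.586, against a mean of 0.136 and a maximum of 0.192 over the 1000 shifts. The longer list of replicate 1 raises the share found from replicate 2. With at least 50% of both regions overlapping, 71.1% of replicate 2 regions and 36.6% of replicate 1 regions were shared, each 6.68 times chance, and with 50% of the replicate 2 region it was 3.27 times. With both lists cut by score to the same length over all sequences, 4329 regions of replicate 2 and 3566 of replicate 1 were left here. Of these, 65.1% of replicate 2 regions and 76.1% of replicate 1 regions were shared. The longer list of replicate 2 lowers the first share and raises the second.

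On the arms and chromosome 4, regions of replicate 1 that replicate 2 lacked were narrow and low in score for that list. These 3773 regions had a median width of 1756 bp and a median score of 0.65, against 3870 bp and 0.93 for the 4629 shared ones. The 212 regions found in replicate 2 alone were alike in kind, with a median width of 1620 bp and a median score of 0.56, against 3938 bp and 0.96 for its shared regions. A wide region meets another by chance more often than a narrow one, and wider regions had higher scores. Part of these gaps therefore follows from counting an overlap of 1 bp as shared, and how much was not tested. Of replicate 2 regions, 875 (20.2%) spanned at least 2 separate regions of replicate 1, and 479 regions of replicate 1 spanned at least 2 of replicate 2.

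Scores ranked matched regions alike in the 2 lists. Over 2543 regions matched 1 to 1 on the arms and chromosome 4, the Spearman correlation of scores was 0.66 and the Pearson correlation 0.64 (permutation p = 1e-05 for each, the smallest the permutations can give). Widths of the same regions had a Spearman correlation of 0.77. Coverage of windows of 100 kb had a Pearson correlation of 0.90 across 1202 windows, and windows of 1 Mb also 0.90 across 118 (permutation p = 1e-05 for each, the smallest). Of the windows of 100 kb, 73 held no region in replicate 1 and 244 held none in replicate 2. Both lists were empty in 71 of them, against 14.8 for independent lists. These correlations are across regions or windows, which are not independent replicates.

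The 5 major arms carried similar shares of H2Av-enriched sequence, and chromosome 4 carried far more. Chromosome 4, a small and largely heterochromatic autosome, had 81.5% of its bases in regions in replicate 1 and 51.3% in replicate 2 (66.4% ± 21.4, SD, n = 2). The 5 major arms together had 26.6% and 19.4% (23.0% ± 5.11, SD, n = 2). The fold of chromosome 4 over the arms was 3.06 in replicate 1 and 2.64 in replicate 2, a mean log2 fold of 1.51 ± 0.15 (SD, n = 2). None of 86 stretches of the same length on the arms reached its mean coverage, and the highest had 54.1% (permutation p = 0.0115, 1-sided, the smallest that 86 stretches can give). The combined list covered 72.1% of chromosome 4.

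Among the major arms, 2R was the most covered, with 29.9% in replicate 1 and 24.4% in replicate 2 (27.2% ± 3.86, SD, n = 2). The means of 2L, 3L, 3R and X were 21.7% ± 5.78, 22.6% ± 6.18, 22.1% ± 4.43 and 22.0% ± 5.29 (SD, n = 2 each). The X chromosome, whose transcription is raised in males by dosage compensation, was not distinguishable from the autosomal arms. Windows of 1 Mb on X had a mean coverage of 22.2% (SD 6.86 over 22 windows) against 23.2% (SD 9.48 over 95 windows) on the autosomal arms. The difference was -0.98 percentage points (bootstrap 95% interval -4.33 to 2.45, permutation p = 0.66, 2-sided), and it was 0.25 in the higher-scoring 50% of each list.

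**Figure D1:**
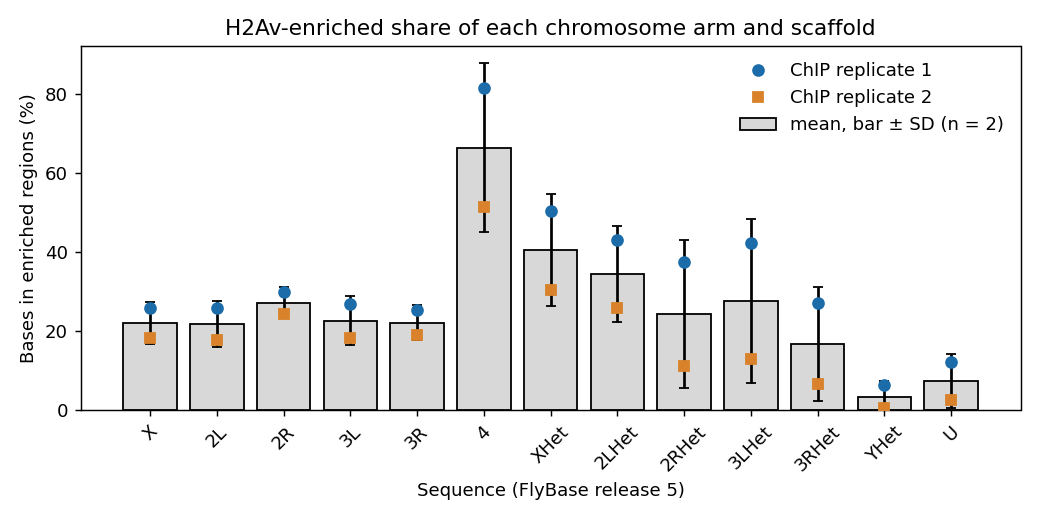
Percent of bases in H2Av-enriched regions (vertical axis) on each arm and scaffold of release 5 (horizontal axis); circles are ChIP replicate 1, squares ChIP replicate 2, and bars the mean with SD over n = 2. Chromosome 4 stands at 66.4% against 21.7% to 27.2% on the 5 major arms, and the replicates lie farthest apart on chromosome 4 (SD 21.4), 3LHet (SD 20.8) and 2RHet (SD 18.7).

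The heterochromatin scaffolds differed between the replicates. Replicate 1 covered 35.3% of the 6 Het scaffolds and replicate 2 covered 10.96% (23.1% ± 17.2, SD, n = 2), and the combined list covered 32.8%. Against the 5 major arms this is a fold of 1.33 in replicate 1 and of 0.565 in replicate 2, so the direction was not the same in the 2 libraries. The mean log2 fold of -0.21 was smaller than its spread of 0.87 (SD, n = 2). Replicate 1 regions held 3.28 Mb of these scaffolds and replicate 2 regions 1.02 Mb. Coverage in replicate 1 over that in replicate 2 was 1.37 on the major arms, 1.59 on chromosome 4, 3.22 on the Het scaffolds and 4.84 on U. The smaller scaffolds 2LHet and XHet had ratios of 1.66 each, and 2RHet, 3LHet and 3RHet had ratios of 3.39, 3.27 and 4.13. YHet, the scaffold of the Y chromosome, held 12 regions in replicate 1 and 1 in replicate 2, over 6.24% and 0.566% of its bases.

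The assembled arm ends next to the centromere were richer in H2Av regions than the rest of the arm on 2L, 2R, 3L and 3R. This comparison was chosen after seeing the data. The Het scaffolds are not part of it. Replicate 2 covered 10.96% of them, less than its 19.4% of the major arms, and replicate 1 35.3%, more than its 26.6%. On 2L the 1 Mb of the assembled arm nearest the centromere was covered to 52.9% ± 16.3 (SD, n = 2), against 20.3% ± 5.30 for the rest of the arm. The corresponding values were 53.7% ± 8.14 against 25.8% ± 3.65 on 2R and 48.0% ± 24.1 against 21.5% ± 5.42 on 3L, where replicate 1 alone gave 65.1% against 25.3% and replicate 2 alone 31.0% against 17.7%. On 3R they were 32.8% ± 15.6 against 21.7% ± 4.02, where replicate 2 alone gave 21.8% against 18.8%. X did not share the pattern, with 20.3% ± 13.7 against 22.1% ± 4.90, and its replicates went opposite ways (30.0% against 25.6% in replicate 1, 10.6% against 18.7% in replicate 2). Over the 5 arms the difference averaged 19.3 percentage points, above the highest of 1000 circular shifts at 15.2 (permutation p = 0.001, the smallest the shifts can give, 1-sided). It was 27.0 points in replicate 1 alone and 11.5 in replicate 2 alone (permutation p = 0.005).

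**Figure D2:**
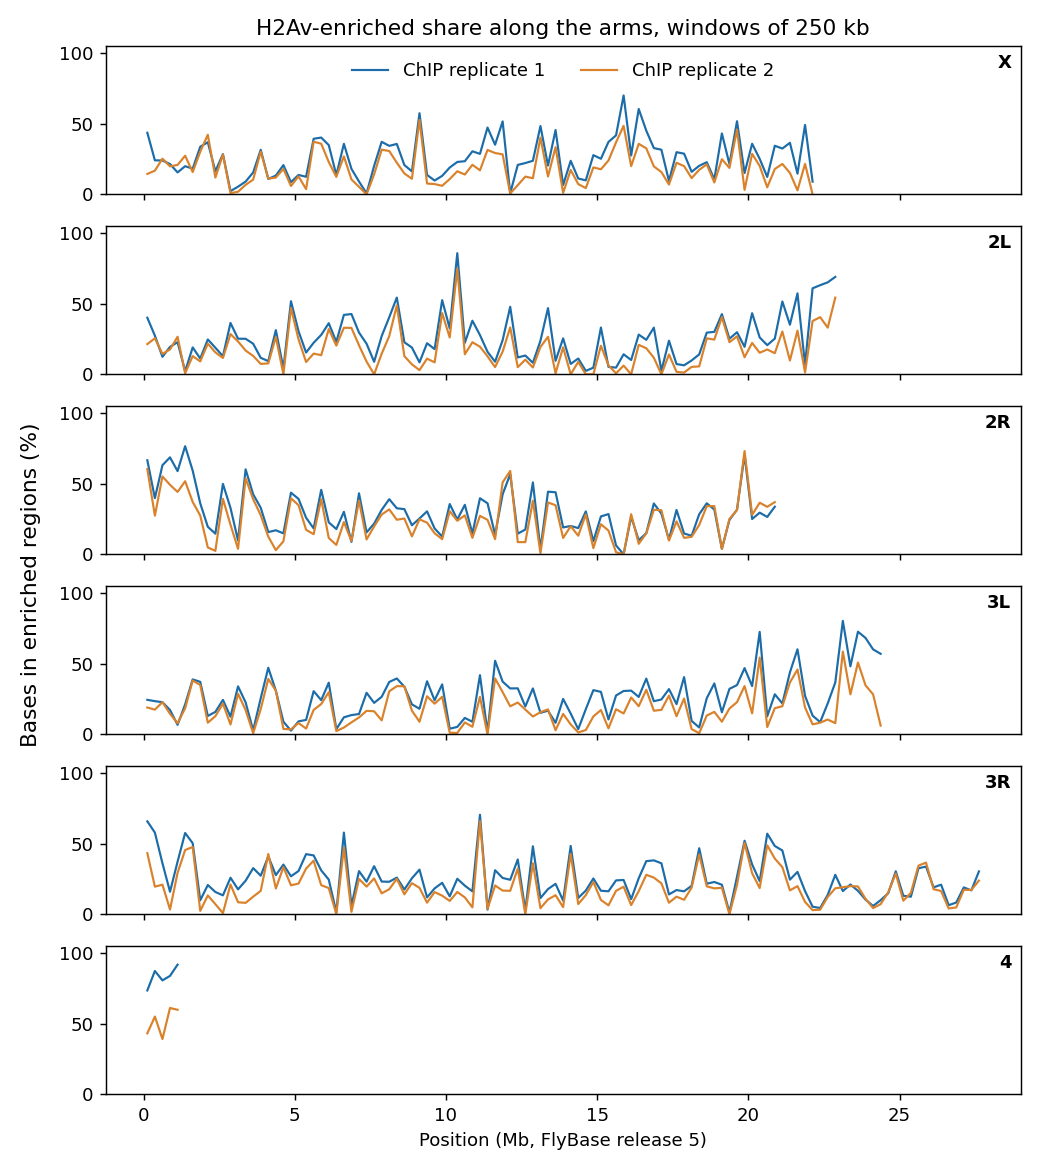
Percent of bases in H2Av-enriched regions (vertical axis) in windows of 250 kb along X, 2L, 2R, 3L, 3R and 4 (horizontal axis, position in Mb on release 5); blue lines are ChIP replicate 1 and orange lines ChIP replicate 2. The 1 Mb of assembled arm nearest the centromere averages 52.9% at the right end of 2L and 48.0% at the right end of 3L. It averages 53.7% at the left end of 2R. Chromosome 4 runs high throughout.

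A larger share of the regions of chromosome 4 than of the major arms was broad. In replicate 1, 33 of its 99 regions (33.3%) reached 10 kb, against 5.64% on the major arms (Fisher's exact test, 2-sided, adjusted p = 2.1e-16 over 3 tests). In replicate 2 these were 20 of 90 (22.2%) against 12.5% (exact test, adjusted p = 0.0098), and in the combined list 24 of 84 (28.6%) against 10.2% (adjusted p = 4.1e-06). Broad regions held 76.3% of the region bases of chromosome 4 in replicate 1 and 61.1% in replicate 2, against 22.2% and 36.0% on the major arms. In replicate 1 chromosome 4 had 73.2 regions per Mb, within the 65.8 to 73.3 of the major arms. Its higher coverage there thus went with wider regions and is not a separate result. In replicate 2 it had 66.6 regions per Mb, against 31.1 to 41.0 on the major arms. Regions on 1 chromosome are not independent replicates.

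The 5 widest regions of the combined list that overlapped both replicate lists all lay on chromosome 4 or in 3L near its centromere. They were not called whole in both replicates. Each overlapped 2 to 8 separate regions of replicate 2, whose widest region was 48525 bp, and 1 to 5 regions of replicate 1. The widest spanned 95.5 kb at position 234636 to 330096 of chromosome 4, of which replicate 1 regions covered 99.7% and replicate 2 regions 86.3%. Others on chromosome 4 lay at 1232428 to 1288438 (56.0 kb) and 977558 to 1031696 (54.1 kb). On 3L they lay at 23216464 to 23283926 (67.5 kb) and 23672782 to 23726796 (54.0 kb).

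The highest-scoring region found in both replicates lay on 3L at 24133136 to 24135718, with a combined score of 4.07. It was followed by 709492 to 719418 on 2R with a score of 2.69 and by 1146020 to 1148320 on 2RHet with 2.39. The other members of the top 10 had scores from 2.14 to 2.30. They lay on U at 9339820 to 9342966, on 3LHet at 1395034 to 1400134 and 587618 to 596014, on 2L at 10402398 to 10409502, on 3L at 24012848 to 24016952, on chromosome 4 at 224576 to 232890 and on 2R at 1177246 to 1198008. Replicate 1 regions covered 75.5% to 100% of each of these 10, except that on 2RHet, of which they covered 24.9%.

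Region scores on chromosome 4, the Het scaffolds and U stood above those of the major arms in replicate 1 and in the combined list, a comparison made after seeing the data. In replicate 1 the median score was 1.28 on chromosome 4, 1.26 on the Het scaffolds and 1.46 on U, against 0.77 on the major arms (permutation test, adjusted p = 1.8e-05 for each over 9 tests). In replicate 2 the medians were 0.90, 0.78 and 0.96 against 0.93, with adjusted p of 0.64, 0.00044 and 0.64 by permutation, and the Het scaffolds were the ones that differed, downward. In the combined list they were 0.90, 0.77 and 1.01 against 0.56 (permutation test, adjusted p = 7.5e-05 for chromosome 4 and 1.8e-05 for the others). Each comparison is within a list, and regions of 1 list are not independent replicates. The combined list is of the same libraries, so it is no separate support for the rise seen in replicate 1. The median width in replicate 1 was 5940 bp on chromosome 4 against 2597 bp on the major arms. Wider regions had higher scores, so part of the rise there may go with width, which was not tested. The Het scaffolds and U had narrower regions, of 2475 and 2036 bp. Of the top 1% of replicate 1 scores, 78.4% lay outside the major arms, and 66.0% were repeated exactly, against 30.3% of the rest. Scores resting on few reads may therefore add to the rise, which was also not tested.

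**Figure D3:**
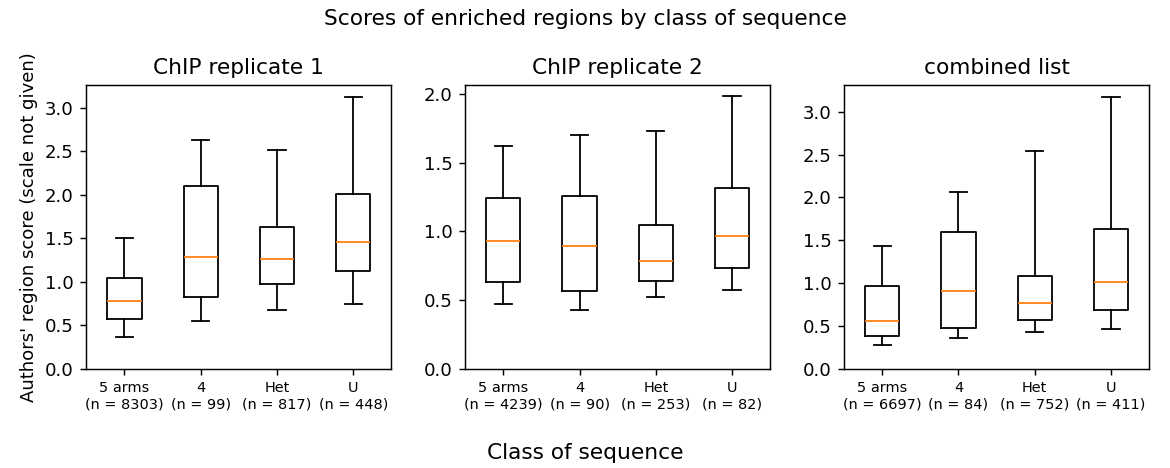
Authors' score of enriched regions (vertical axis, scale not given) on the 5 major arms, chromosome 4, the Het scaffolds and U (horizontal axis), a panel per list with its own scale; lines mark medians, boxes the middle 50% and whiskers 5% and 95%. In replicate 1 the median rises from 0.77 on the major arms to 1.46 on U, and in replicate 2 the 4 medians lie between 0.78 and 0.96.

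Regions clustered along the arms and left long stretches empty, a result also added after seeing the data. On the 5 major arms 146 stretches of at least 100 kb held no region of replicate 1, against 0.68 on average and 5 at most when regions were placed at random (permutation p = 0.001, the smallest the placements can give, 1-sided). Replicate 2 left 282 such stretches empty against 53.8 and 75 at most (permutation p = 0.001, the smallest). At 50 kb it left 509 empty, against a random mean of 465.4 and a maximum of 508 (permutation p = 0.001, the smallest). The longest stretches empty in all 3 lists were 496 kb on 2R at 15617008 to 16112671, 290.4 kb on X at 12010307 to 12300721 and 268 kb on 3L at 4838265 to 5106327.

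The combined list held nearly all of replicate 2 and most of replicate 1. It overlapped 4287 of 4329 replicate 2 regions, or 99.03% (98.7 to 99.3), and 6753 of 8402 replicate 1 regions, or 80.4% (79.5 to 81.2). Of its own 6781 regions on the arms and chromosome 4, 55.3% overlapped both replicates, 32.2% replicate 1 alone, 3.23% replicate 2 alone and 9.22% neither. Regions shared with both had a median width of 5037 bp, against 1681 bp for those shared with replicate 1 alone and 1193 bp for those shared with neither. On the Het scaffolds 21.3% of its 752 regions overlapped both replicates, 60.5% replicate 1 alone, 0.93% replicate 2 alone and 17.3% neither.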

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

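All alternatives for X in windows of 500 kb or 100 kb, for the sequence next to the centromere, for empty stretches and for scaffolds pooled with U were chosen after seeing the data. Replicate overlap, score correlation and the higher coverage of chromosome 4 kept their direction and their side of the threshold under every alternative run. So did the higher coverage of the assembled arm ends next to the centromere. The share of replicate 2 regions found in replicate 1 ran from 65.1% to 95.1% and that of replicate 1 regions found in replicate 2 from 36.6% to 76.1%, the overlap over chance from 1.89 to 6.68 times, the Spearman correlation of scores from 0.46 in the higher-scoring 50% of each list to 0.70 (0.77 for widths), the log2 fold of chromosome 4 from 1.40 to 1.78, and the difference next to the centromere from 11.5 to 27.0 points. The log2 fold of the Het scaffolds over the arms ranged from -0.82 to 0.41 with either replicate left out, because the replicates differ in sign. It was -0.88 with U added to the scaffolds, 0.046 with lists cut by score to the same length and 0.32 in the combined list, and the cause of these was not tested. X minus the autosomal arms turned to 0.25 points in the higher-scoring 50% of each list, with an interval that included 0 in every setting, and the cause was not tested. Empty stretches of at least 100 kb in replicate 1 rose from 146 to 267 in the higher-scoring 50% and 277 with lists cut to the same length, because fewer regions were left. They exceeded random placement there too, as did stretches of at least 200 kb in both replicates and of 50 kb in replicate 1, while at 50 kb replicate 2 had 509 against a random maximum of 508. The share of combined-list regions found in both replicates was 50.0% with 50% of the region overlapping and 61.6% in the higher-scoring 50% of each list, and the cause of the second was not tested. No paired analysis was possible because the input libraries have no values of their own here and each region list already sets a ChIP library against its input. Alternatives for genomic features, start sites, marked genes, gene lists and scores at start sites were not run, since no gene positions on release 5 were used here. Read depth is unknown, so whether the shorter list of replicate 2 comes from fewer reads could not be examined.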

Other observations

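The test with repeated scores removed was chosen before its result was seen, and the others in this part were chosen after.

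Regions found 1 to 1 in both lists held different places in their own lists depending on where they lay. The 111 such regions on the Het scaffolds had a median score percentile of 88.7 in replicate 1 and of 40.8 in replicate 2. The 26 on chromosome 4 stood at 94.98 and 55.9, and the 2517 on the 5 major arms at 62.1 and 53.6. The lists differ in length, so these ranks describe each list and do not measure a change. The 1 Mb nearest the centromere of the 5 arms, on average, was covered to 52.6% in replicate 1 and 30.5% in replicate 2, a ratio of 1.72, against 1.35 for the rest of the arms.

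The Het scaffolds were covered more in replicate 1 than in replicate 2 beyond the difference on the arms, by 1.23 on the log2 scale (bootstrap 95% interval over windows 0.94 to 1.60). A smaller number of calls in replicate 2 stays open, since cutting replicate 1 by score to as many regions gave 1.74 (1.46 to 2.10) but keeps its high-scoring scaffold regions by construction. Scores that repeat exactly, as ratios of small counts would, are unlikely to account for it by themselves. Without them the difference was 1.17 (0.90 to 1.52), where a value under 0.58 was needed. That removal kept 69.3% of replicate 1 regions and 90.3% of replicate 2 regions. Regions that rest on few reads but have a score of their own stayed in, so few reads as a source stay open. A weaker signal of heterochromatin in the second library could account for it, and shared regions there dropped 33.6 percentile points more than on the arms (27.8 to 36.9), but this stays open because ranks from lists of different length can move with the length alone. The input libraries, the treatment of repeated sequence and the larvae collected stay open, and no biological explanation was tested, since the design has 1 ChIP group.

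The highest scores belonged to narrow regions. The top 1% of the combined list had a median width of 1001 bp, its minimum, against 2847 bp for the rest, and 62.0% of it lay outside the 5 major arms against 15.2%. Of these scores 97.8% were repeated exactly in another region, against 16.6% of the rest. That is consistent with scores that rest on few reads, and such regions may not mark strong H2Av binding. In the replicate lists the repeated shares were 66.0% against 30.3% in replicate 1 and 29.8% against 9.49% in replicate 2, and no biological explanation was tested.

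Of the combined list, 625 regions on the arms and chromosome 4 and 130 on the Het scaffolds overlapped neither replicate list. On the arms and chromosome 4 their scores had a median percentile of 22.8, low enough for weaker regions that may pass once reads are pooled. Regions found in replicate 1 alone stood at 27.4 and in replicate 2 alone at 13.3, so those in neither list were not the lowest. The pooling of reads alone leaves that unexplained. The minimum width was 1301 bp in both replicate lists and 1001 bp in the combined list. Regions in neither list had a median width of 1193 bp here, so most were narrower than any replicate region. How much this difference in minimum width contributes was not tested. On the Het scaffolds, regions in neither list had a median percentile of 81.9 and a median width of 1183 bp. This width is also under the 1301 bp minimum of the replicate lists, and high scores of narrow regions may rest on few reads. The percentile there neither excludes pooling as an explanation nor bears it out. Whether the authors pooled reads is not given in the sources used here, and no biological explanation was tested.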
